A study of Mus musculus with 18 samples.

How the data were processed

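Coding joins on an integrated pMX-INV recombination substrate were measured by HTGTS in v-abl-transformed mouse B cells of 4 genotypes, with 1 G1-arrested and 2 G2-arrested libraries per genotype. Per the labels' protocols, genomic DNA was sonicated, amplified linearly with a biotinylated bait primer, amplified again with a nested primer and treated with BstBI to remove germline substrate, and sequenced on a MiSeq. Also per the labels' protocols, reads were aligned to mm10 with the substrate added as an extra chromosome, and the submitters' processing notes name Bowtie2 and mm10. Versions and the junction caller, with its filters and its handling of duplicates, were not given in the sources used here. The substrate sequence was not used here apart from what the reads themselves show.

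Each deposited table lists 1 junction per line, and per the file headers its columns give the prey chromosome, position and strand, the bait end, the read positions of both alignments (base positions, no normalization), the read sequence and a set of filter columns. Of the filter columns, 8 were 0 in every line. Whether those filters had been applied before deposit or were never run cannot be told from the lines themselves. The deposited uncut column, a count of bases aligned past the break site per the file headers, was above 0 in 118 lines. The shortest prey alignment was 20 bp. No read carried more than 1 junction and no read name was repeated. Depth is the number of junctions per library, from 289 to 7068, with 30937 in all. Repeat lines, those beyond the first with the same prey position, strand and bait end, made up 12.5% to 18.9% of the libraries with DNA-PKcs and 5.23% to 7.00% of those without it. Positions were compared with GRCm38.p6, the sequence behind mm10. Over 21877 genome junctions, 98.1% of the bases marked as matching equalled the reference and 98.6% of junctions had every such base equal.

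Samples were grouped by the genotype and phase in their labels. The 6 samples with breaks made by the I-PpoI endonuclease are not analysed here. Sequencing run was taken from the read names, and run 1 held the first G2 replicate of each genotype while run 2 held the second G2 replicates and the G1 libraries.

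Values per library were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Genes were named from GENCODE mouse M21. The coding ends were set at the most frequent bait end and prey position, each library weighted equally. A coding join was a substrate junction on the strand of the main prey peak within 1000 bp of it. This window includes joins onto the inverted bait, 3.03% to 9.46% of substrate junctions, which count as deletions of 0 bp. Deletion was the distance in bp from each coding end, homology the overlap of the bait and prey alignments on the read, and insertion the gap between them. A palindromic insertion repeated the adjoining end as reverse complement over 3 bp or more. Shares of single libraries carry 95% Wilson intervals, and a count of 0 allows up to 3 counts of the total.

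Before the data were examined, 12 measures, the tests, the lists and most alternatives were fixed. The CtIP, DNA-PKcs and phase effects are differences averaged with equal weight over strata (4 each) and tested by permuting labels within strata, two-sided and exactly, over 144, 144 and 81 arrangements. The smallest p values are 0.0139 and 0.0123, with no group pair of 2 against 2 able to reach 0.05 alone. The interaction was tested over the same 144 arrangements with CtIP labels permuted, so its null is no CtIP effect with or without DNA-PKcs. P values were adjusted by Benjamini-Hochberg over the 12 measures of a comparison, with a threshold of 0.05. Intervals of differences come from inverting the permutation test. The rule for named loci took the 6 antigen receptor loci, 8 translocation partner genes, 3 genes that share sequence with constructs, the 10 megabase bins with the highest mean share of genome junctions among bins seen in 3 or more libraries, and the 5 substrate positions with the highest mean share. Jκ joins were counted from 5 bp before to 50 bp after a segment start on the coding side, and over the 50 bp before it on the signal side. Jκ joins, telomere repeats, joins onto the bait's own signal side and local clusters were chosen after the data were examined, and p values of these added classes are not adjusted.

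A telomere-repeat junction had at least 3 exact repeat units in its prey alignment. To count events, lines with the same bait end and the same following 12 read bases, with up to 2 differing bases tolerated, counted once. Local clusters were 200 kb windows with at least 10 junctions and 2% of a library's genome junctions without telomere repeat, taken with 100 kb on either side, and their strand order was tested against 10000 shuffles of the strands. Junctions in antigen receptor loci were left out, and so were windows whose joins were stacked within a short span.

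The permutation test was tested on 1 simulated measure in 12 libraries with a spread of 5.37 points, that of the insertion share between G2 replicates, in 200 runs per setting. With no difference, the unadjusted p fell under 0.05 in 5% (CtIP), 3.5% (DNA-PKcs) and 6.5% (phase) of runs. With 20 points it did so in 100%, 98.5% and 100%. The counting of 8 measures was tested on 400 simulated lines, and all 8 equalled the simulated values.

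Alternatives counted identical junctions once, left out lines with uncut bases or prey alignments under 30 bp, used log odds, thinned libraries to the smallest, blocked by replicate number and left out each library. Others changed the window, the deletion thresholds, the palindrome length, the denominator of homology and the counting of antigen receptor positions, or kept G2 libraries only. Trimming at the heptamer borders and keeping coding-side joins only (each alone and both together), leaving out telomere repeat and using 1 sequencing run were added after the data were examined.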

Results

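Repair junctions were mapped in v-abl-transformed mouse B cell lines, precursor B cells immortalised by a viral Abl kinase. Each line carried an integrated pMX-INV substrate, a construct with a pair of recombination signal sequences for the RAG nuclease, which such lines express once the Abl kinase is inhibited. High-throughput genome-wide translocation sequencing (HTGTS) reads outwards from a fixed bait primer beside 1 RAG break and records what each broken end was joined to, the prey. The 12 coding-join libraries covered 4 genotypes, namely wild type, CtIP A/A, DNA-PKcs −/− and CtIP A/A DNA-PKcs −/−. CtIP promotes resection of DNA ends, and the A/A allele carries alanine at the conserved ATM/ATR phosphorylation site that the series addresses. DNA-PKcs is the kinase of classical non-homologous end joining that acts with Artemis to open hairpin-sealed coding ends. Cells of each genotype were held in G1 with the Abl inhibitor STI571 (3 µM for 48 or 72 h, 1 library) or moved after 24 h of STI571 into the CDK1 inhibitor RO3306 (10 µM for 48 h) for a G2 arrest (2 libraries).

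The libraries held 30937 junctions. Wild type gave 2993 junctions in G1 and 535 and 289 in G2, and CtIP A/A gave 834 in G1 and 535 and 586 in G2. DNA-PKcs −/− gave 5042 in G1 and 3663 and 2381 in G2, and the double mutant gave 7068 in G1 and 4170 and 2841 in G2. A library of 289 junctions with no hit allows a share of up to 1.04%, and one of 7068 allows up to 0.0424%. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The labels do not say that replicates came from separate cultures or lines, so p-values measure the spread between these samples, which may be technical, and genotype is not separable from cell line. The junction tables carry no measurement of CtIP or DNA-PKcs themselves, so each genotype rests on its label.

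On the substrate, the joins centred on the borders of the paired signal sequences. Heptamers of sequence CACTGTG lay at substrate positions 1936 to 1942 on the bait side and 2806 to 2812 on the partner side, so that the first coding bases were 1943 and 2813. The most frequent bait end was 1947 and the most frequent prey position was 2811, over the 12 libraries as well as in the wild-type G1 library alone. The 5 most used prey positions were 2811, 2812, 2815, 2829 and 2821. Position 2811 took 10.4% ± 2.28 (SD, n = 6) of the substrate junctions in the libraries with DNA-PKcs and 3.05% ± 0.534 (SD, n = 6) in those without it. Position 2812 took 7.97% ± 1.90 against 0.919% ± 0.170, position 2815 took 4.90% ± 1.11 against 1.60% ± 0.529, and position 2821 took 4.22% ± 0.881 against 1.95% ± 0.379. Position 2829, which is 16 bp into the coding sequence, took 2.20% ± 0.679 with DNA-PKcs and 4.08% ± 1.02 without it. These 5 positions were described and not tested.

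The comparison of DNA-PKcs −/− with DNA-PKcs-present libraries asked how coding ends are joined when classical end joining is impaired. Without DNA-PKcs, coding joins lost more sequence on both sides of the break. The median deletion from the partner coding end was 18.0 bp ± 2.68 (SD, n = 6) without DNA-PKcs and 4.67 bp ± 1.51 (SD, n = 6) with it. Partner-end deletions over 20 bp rose from 10.6% ± 5.21 to 41.9% ± 8.07 of coding joins, and bait-end deletions over 20 bp rose from 16.7% ± 2.36 to 49.2% ± 11.2 (SD, n = 6 each). Joins with inserted bases, the class that holds N nucleotides, fell from 61.4% ± 3.38 to 22.4% ± 5.36. P nucleotides count in that class only where they did not align to the substrate. Both coding ends begin with CAG and both heptamers end with TG, so the P nucleotides G and TG align as heptamer bases. Direct joins rose from 13.9% ± 0.612 to 33.4% ± 2.68, and joins with at least 1 bp of microhomology rose from 24.7% ± 3.41 to 44.2% ± 6.48.

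Each of these measures separated the 6 DNA-PKcs −/− libraries from the 6 others and gave p = 0.0139 in a two-sided exact permutation test of 12 measures, the smallest p the design allows (adjusted p = 0.0238). Averaged over the 4 strata of CtIP genotype and arrest phase, the median partner deletion was longer by 13.6 bp (95% interval 12 to 16). The share over 20 bp was higher by 32 points (26.0 to 36.8) at the partner end and by 34.7 points (19.9 to 42.9) at the bait end. Direct joins were higher by 20.1 points (16.2 to 22.7) and microhomology joins by 19.7 points (10.9 to 26.4), and insertions fell by 39.9 points (interval −45.7 to −31.1). Within sequencing runs 1 and 2, partner deletions over 20 bp differed by 33.7 and 30 points and insertions by −37.6 and −39.6 points. With inserted joins left out of the denominator, the direct joins were higher by 7.19 points and the microhomology joins differed by −7.19 points (adjusted p = 0.0556, exact permutation).

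**Figure D1:**
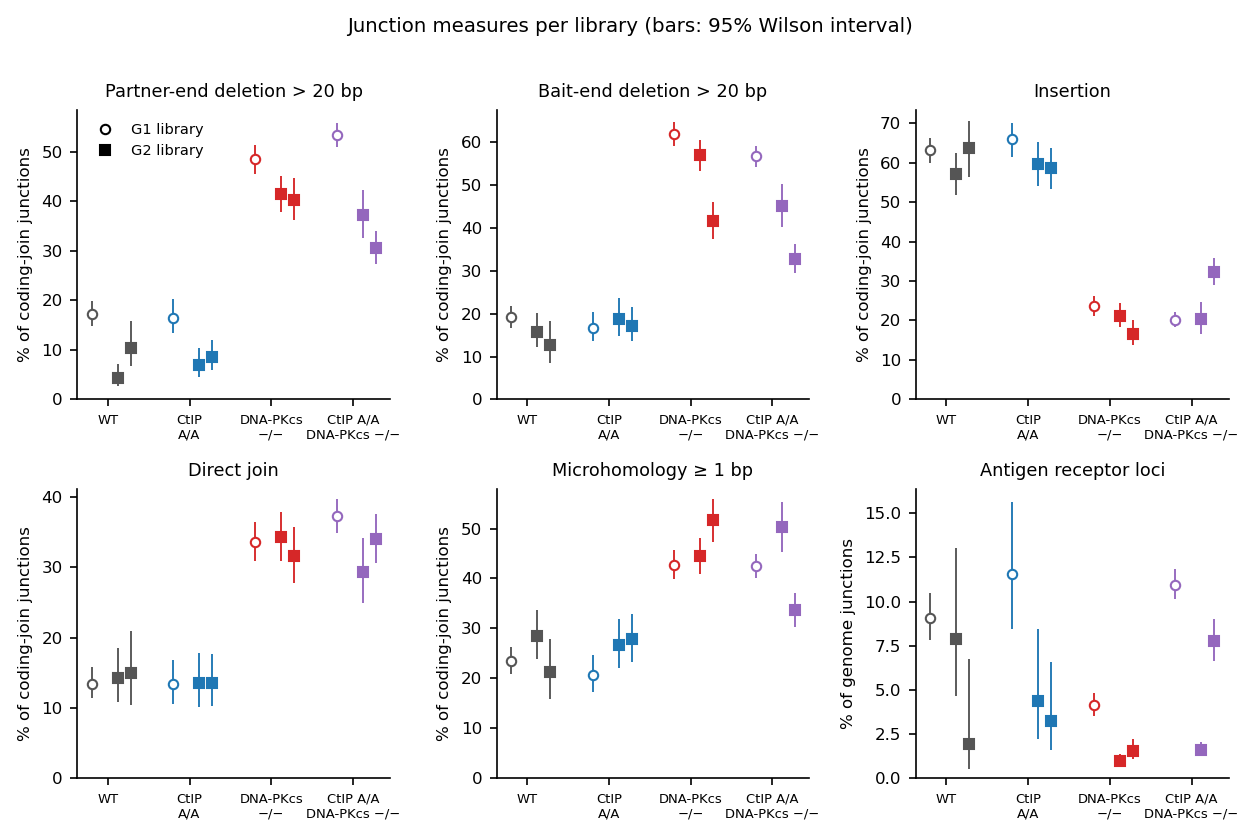
Percent of coding-join junctions (or, in the last panel, of genome junctions) with each property in each of the 12 libraries, grouped by genotype; open circles are G1 libraries, filled squares G2 libraries, and bars 95% Wilson intervals. The 6 DNA-PKcs −/− libraries lie apart from the 6 others in the deletion, insertion, direct-join and microhomology panels, with insertions at 16.7% to 32.4% against 57.1% to 65.9%.

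Partner deletions over 200 bp and homologies of 4 bp or more did not pass the threshold between DNA-PKcs groups. Partner deletions over 200 bp made up 1.66% of coding joins without DNA-PKcs and 2.36% with it (stratum means; difference −0.702 points, interval −3.10 to 2.07). At a threshold of 100 bp the difference in partner deletions was 1.67 points (adjusted p = 0.130, exact permutation). Microhomology of 4 bp or more made up 7.48% without DNA-PKcs and 8.88% with it (adjusted p = 0.0926, exact permutation). That measure depended on which joins were counted and on how the heptamer was read. In settings fixed before the data were examined, the difference was −3.12 points with identical junctions counted once, −1.80 after the filter on uncut bases and short alignments and −13.7 without inserted joins (adjusted p = 0.0208, 0.0417 and 0.0278, exact permutation). With the replicate block, also fixed beforehand, it was −1.40 points (adjusted p = 0.0469, exact permutation). The other settings were chosen after the data were examined. With only coding-side joins kept the difference was 0.883 points, and with alignments only trimmed at the heptamer borders it was −0.0609 points (adjusted p = 0.130 and p = 0.917, exact permutation). With both choices together, homologies of 4 bp or more made up 3.15% without DNA-PKcs and 0.733% with it (adjusted p = 0.0208, exact permutation), and joins with at least 1 bp of microhomology made up 37.6% and 11.4%. Palindromic insertions of 3 bp or more made up 0.182% and 0.662% (p = 0.0417, adjusted p = 0.0625, exact permutation). Palindromes whose first bases aligned to the heptamer are missed by this count.

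**Figure D2:**
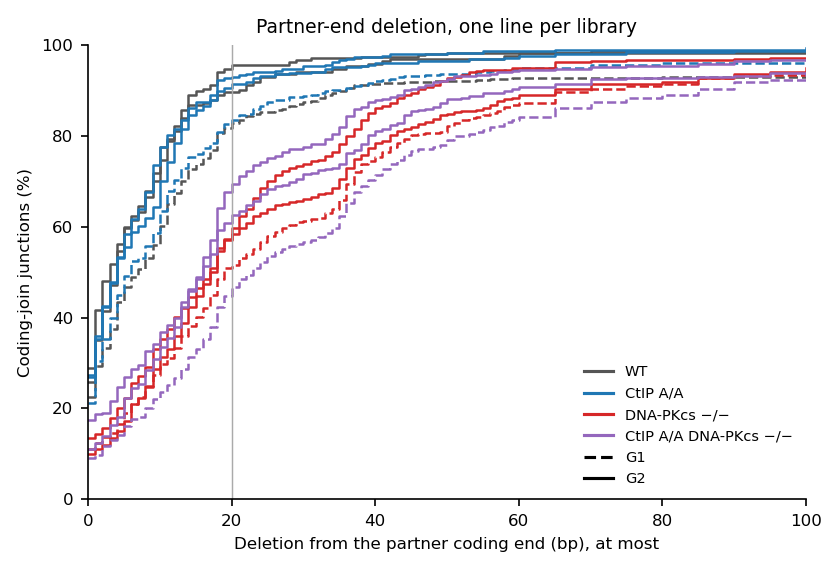
Cumulative percent of coding-join junctions (vertical axis) with at most the given deletion in bp from the partner coding end (horizontal axis), with 1 line per library; colours mark genotypes, broken lines G1 and solid lines G2, and the grey line marks 20 bp. Libraries with DNA-PKcs had 4.35% to 17.2% of joins beyond 20 bp and those without it 30.6% to 53.3%, and G1 lines lie below the G2 lines of their genotype at 20 bp.

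The comparison of CtIP A/A with CtIP wild type asked whether the CtIP phosphorylation site alters how RAG-generated ends are processed. No measure of coding joins set the CtIP A/A libraries apart from the CtIP wild-type libraries. In the DNA-PKcs-present cells, partner deletions over 20 bp made up 7.69% ± 1.08 (SD, n = 2) of G2 joins in CtIP A/A and 7.35% ± 4.24 (SD, n = 2) in wild type, and 16.5% and 17.2% in the single G1 libraries. Insertions made up 59.2% ± 0.796 of G2 joins in CtIP A/A and 60.5% ± 4.70 in wild type. In DNA-PKcs −/− cells, the G2 share of partner deletions over 20 bp was 33.9% ± 4.75 with CtIP A/A and 40.9% ± 0.833 with wild-type CtIP, whereas the G1 shares were 53.3% and 48.5%.

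None of the 12 measures passed the threshold in the exact permutation test over 4 strata, and 0 reached an unadjusted p under 0.05. The intervals of the difference, CtIP A/A minus wild type, ran from −7.13 to 4.11 points for partner deletions over 20 bp and from −11.6 to 4.56 points for bait deletions over 20 bp. They ran from −3.15 to 2.39 points for direct joins, from −9.94 to 5.81 points for microhomology joins, and from −3.97 to 9.11 points for insertions. The median partner deletion differed by 0.625 bp (−0.995 to 3.00). Within sequencing runs 1 and 2, partner deletions over 20 bp differed by −0.784 and −1.84 points and insertions by 0.869 and 2.46 points. The smallest p belonged to antigen receptor loci, which took a mean of 7.76% of genome junctions in CtIP A/A and 4.84% in wild type (difference 2.92 points, interval −2.26 to 6.79, p = 0.139, exact permutation). Over the alternatives, log odds aside, that difference ran from −1.41 points (run 1 alone) to 5.77 points (telomere-repeat junctions left out). The lowest unadjusted p among them was 0.0139 and the lowest adjusted p was 0.167 (exact permutation). Libraries were simulated for 1 measure with a spread of 5.37 points, that of the insertion share between G2 replicates. A CtIP difference of 10 points reached an unadjusted p under 0.05 in 71.5% of runs and a difference of 5 points in 25.5% (exact permutation). The threshold applied to the 12 measures, after adjustment, is stricter and was not simulated.

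The design also asked whether the CtIP effect differs with DNA-PKcs status. None of the 12 measures passed the threshold, and 1 reached an unadjusted p under 0.05 in the exact permutation test. Partner deletions over 200 bp were 2.38 points less frequent with CtIP A/A in DNA-PKcs-present cells (difference −2.38) and 0.310 points more frequent in DNA-PKcs −/− cells. The difference between these effects was 2.69 points (p = 0.0278, adjusted p = 0.333, exact permutation against no CtIP effect in either background). It rested in part on the wild-type G1 library, in which 5.91% of coding joins (54 of 914, 95% Wilson interval 4.56 to 7.63) had such deletions. Without the G1 libraries of the DNA-PKcs-present cells the difference was 1.35 points (p = 0.0556, exact permutation).

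The comparison of G2 with G1 asked whether the arrest point changes joining. In each of the 4 genotypes, partner ends were deleted less in G2 than in G1. The stratum-averaged median partner deletion was 10.1 bp in G2 and 13.8 bp in G1 (difference −3.63 bp, interval −5.50 to −2.01). Partner deletions over 20 bp fell from 33.9% in G1 to 22.5% in G2 (difference −11.4 points, −16.7 to −6.78). In wild type the share was 17.2% in G1 and 7.35% ± 4.24 (SD, n = 2) in G2, and in the double mutant it was 53.3% in G1 and 33.9% ± 4.75 in G2. Junctions in antigen receptor loci fell from 8.93% of genome junctions in G1 to 3.67% in G2 (difference −5.26 points, −9.33 to −1.20). Some G2 counts were small, with 13 of 165 and 2 of 104 in wild type, against 165 of 1817 in G1.

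These 3 of 12 measures gave p = 0.0123 in the exact permutation test over 4 genotypes, the smallest p the design allows (adjusted p = 0.0494), and G2 was lower in 4 of 4 genotypes for each. At that p no measure could have passed the threshold alone, so the adjusted value rests on all 3 reaching it. Both deletion measures describe the same partner deletions. The first G2 replicates were sequenced in another run than the remaining libraries. Within the run that held both phases, the G2 minus G1 differences averaged −3.50 bp (range −7 to −2) for the median deletion, −11.5 points ± 7.55 (SD, n = 4 genotypes) for deletions over 20 bp and −5.31 points (−8.28 to −2.59) for antigen receptor loci, again with all 4 genotypes below 0. The adjusted p rose above 0.05 for all 3 when any 1 library was left out (up to 0.222 for both deletion measures and 0.333 for antigen receptor loci). It also did so on the log odds scale, after the filter on uncut bases and short alignments, and after thinning to the smallest library (0.0741 to 0.185). In those settings both deletion measures kept an unadjusted p of 0.0123, and that of antigen receptor loci rose to between 0.0247 and 0.0494 (exact permutation). For antigen receptor loci without telomere repeat the adjusted p was 0.0988. Bait deletions over 20 bp made up 30.1% in G2 and 38.7% in G1 (p = 0.111, exact permutation). Insertions, direct joins and microhomology joins differed between the phases by −1.95, −1.25 and 3.20 points (adjusted p of 0.510 or more, exact permutation).

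The junctions outside the substrate show which genome sequences the recovered bait ends were joined to. Ends left unjoined give no junction, so all shares are of recovered junctions. The substrate took 60.9% ± 10.8 (SD, n = 6) of all junctions with DNA-PKcs and 24.0% ± 7.18 (SD, n = 6) without it (stratum-averaged difference −33.9 points, interval −50.5 to −19.1, adjusted p = 0.0238, exact permutation). Much of the remainder without DNA-PKcs consisted of prey sequence made of the telomere repeat, at least 3 units of 6 bp, a class defined after the data were examined. Telomere-repeat junctions made up 56.5% ± 14.1 (SD, n = 6) of all junctions in the DNA-PKcs −/− libraries (38.4% to 76.7%) and 4.79% ± 3.55 (SD, n = 6) in the others (0.959% to 9.91%). The stratum-averaged difference was 50.7 points (p = 0.0139, exact permutation), and it held within run 1, where the shares were 67.6% and 76.7% without DNA-PKcs and 8.41% and 9.91% with it. Many such lines shared a bait end and the bases that follow it, and with each such event counted once the shares of distinct junctions were 11.4% ± 6.52 and 2.84% ± 1.28 (difference 7.81 points, p = 0.0139, exact permutation). With telomere-repeat junctions left out of the total, the substrate share differed by −6.28 points (adjusted p = 0.439, exact permutation).

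**Figure D3:**
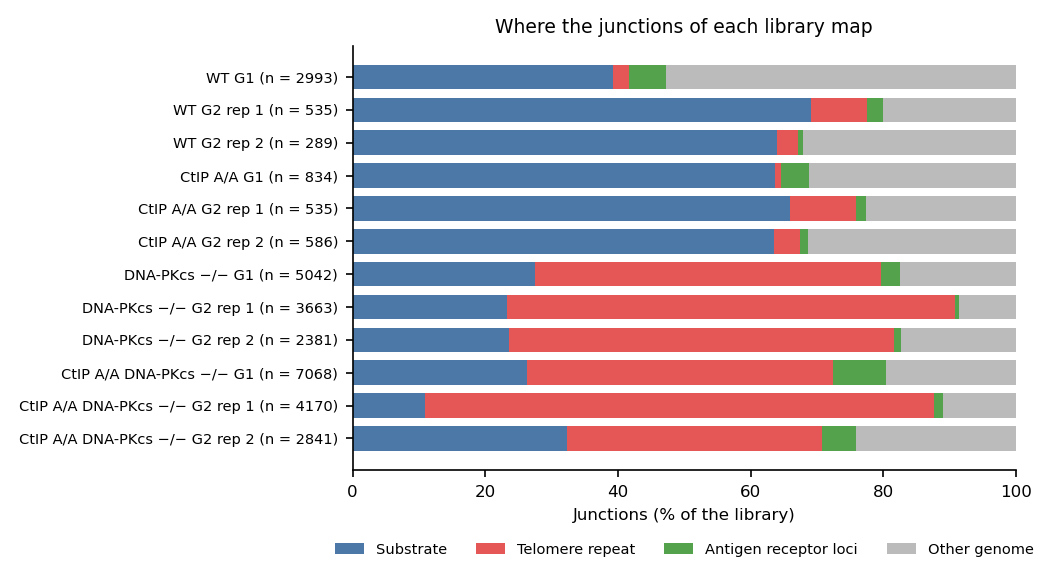
Percent of all junctions of each library (horizontal axis) that map to the substrate, to telomere repeat, to antigen receptor loci or elsewhere in the genome, with the junction total of each library in brackets. Telomere repeat takes 38.4% to 76.7% of the junctions in the 6 DNA-PKcs −/− libraries and 0.959% to 9.91% in the 6 others.

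The 6 antigen receptor loci, which carry the natural RAG targets, held 1216 junctions over the 12 libraries. The double mutant G1 library alone held 571 of them. The light chain locus Igk (chromosome 6, 67555497 to 70726966, mm10) held 1001 of the 1216, and the heavy chain locus Igh (chromosome 12, 113254830 to 116010093) held 135. Igk junctions occurred in all 12 libraries but unevenly, with 514 in the double mutant G1 library and 2 to 5 in each G2 library with DNA-PKcs. Igl held 46, Tcrg 24, Tcra/Tcrd 7 and Tcrb 3. At the Jκ segments, 250 junctions lay on the coding side of a segment border and 89 on the signal side, with Igkj1 (70722562 to 70722599) taking 145 and 26, Igkj2 56 and 31, Igkj4 31 and 22, and Igkj5 18 and 10. Igkj3 had none on either side. In the libraries with DNA-PKcs the Jκ counts were 34 on the coding side and 23 on the signal side, and in those without it 216 and 66. These Jκ counts pool libraries of unequal depth and are not averages over libraries. Antigen receptor loci took 5.25% of genome junctions without DNA-PKcs and 7.34% with it (stratum means; adjusted p = 0.300, exact permutation). With telomere-repeat junctions left out, the share was 7.68 points higher without DNA-PKcs (adjusted p = 0.0926, exact permutation).

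Few junctions lay in the other genes listed beforehand. Of the translocation partner genes, Notch1 had 6 junctions in 5 libraries and Pax5 had 1, and none was seen at this depth in Myc, Pvt1, Ccnd1, Ccnd2, Bcl6 or Mycn. Of the genes that share sequence with constructs such lines may carry, Bcl2 had 1 junction and Abl1 and Cd4 had none. Of the 10 megabase bins with the highest mean share of genome junctions, 8 were filled to 88.0% or more by telomere repeat, where the mapped position of a repeat is not a location. They began at 113000001 on chromosome 9 (2.96% of genome junctions), 170000001 on X, 73000001 on 1, 98000001 on 16, 110000001 on 13, 153000001 on 4, 130000001 on 10 and 90000001 on Y (0.998%). The remaining 2 held no telomere repeat. The bin from 70000001 on chromosome 6 (2.46%) had 567 of its 586 junctions within Igk, with 172 in Gm30211. The double mutant G1 library held 316 of the 586. The bin from 167000001 on chromosome 2 (1.30%) had 276 junctions in 7 libraries, of which 96 lay in Tmem189.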

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

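The tests of telomere-repeat joins, of joins onto the bait's own signal side and of local clusters were chosen after the results were seen.

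Telomere-repeat prey, a signal outside the planned measures, made up 56.5% of all junctions in the DNA-PKcs −/− libraries against 4.79% in the libraries with DNA-PKcs. Repeated reads may inflate the share, with 11.2 to 14.6 lines per event without DNA-PKcs and 1.14 to 3.46 with it. Independent joins at 1 bait end in the same repeat phase also count as 1 event, so these values cannot tell the 2 apart. Other junctions without DNA-PKcs had 1.04 to 1.08 lines per distinct junction. Counting repeated lines once lowered the difference without removing it. With each event counted once the libraries still separated, by 7.81 points (p = 0.0139, exact permutation). With each bait end counted once the difference was 2.13 points (p = 0.0417, exact permutation, not adjusted). In that count the groups overlapped, at 2.04% to 8.76% without DNA-PKcs and 0.850% to 3.88% with it. Of the 14251 junctions, 99.7% read CCCTAA from the bait, the direction from a chromosome end inwards, which argues against joins to repeats inside chromosomes, where both directions would occur, and only 0.288% read TTAGGG, which argues against repeats added to the broken end by telomerase. A candidate explanation is that broken coding ends were joined to chromosome ends in cells that lack DNA-PKcs. Whether the genotype or the cell line carries this stays open, as does how far copying of repeats during amplification adds to the count of events.

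Some DNA-PKcs −/− libraries held dense local clusters of genome joins, again outside the planned measures. Shares are of genome junctions without telomere repeat. On chromosome 2 around 167764881, in intergenic sequence, a cluster took 28.0% in DNA-PKcs −/− G2 replicate 1 and 9.15% in the G1 library of that genotype. Of the wild-type libraries, G1 had 4.07% there and G2 replicate 1 had 5% (6 of 120, 95% Wilson interval 2.31 to 10.5). On chromosome 3 around 107853190, also intergenic, a cluster took 21.9% in the double mutant G2 replicate 2. In DNA-PKcs −/− G2 replicate 2, clusters took 11% on chromosome 4 around 133671511 (an intron of Pigv), 12.1% on chromosome 7 around 101228817 (an intron of Fchsd2) and 5.26% on chromosome 5 around 140217723 (an intron of Mad1l1).

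At least 92.5% of the joins in each of the 6 ordered clusters lay at distinct positions. Windows with joins stacked in a short span had been left out beforehand, so repeated reads of 1 join could not have formed a cluster. The value shows only that few joins in the kept clusters shared a position. DNA-PKcs −/− G2 replicate 2 had 0 of 437 junctions in the chromosome 2 cluster, which allows up to 0.686%, against 94 of 336 in G2 replicate 1, so a region joined in every library is not enough. In the 6 clusters of DNA-PKcs −/− libraries with joins on both strands, at 5 loci, joins on the minus strand lay below and joins on the plus strand above 1 point more often than with shuffled strands (80.5% to 97.9% of joins in order, p = 0.0003 or less in a permutation test of 10000 shuffles), and 1 cluster with joins on 1 strand only could not be tested. This is what a break at 1 point would give, and the place where the substrate is integrated may be that point. The labels name no integration site, so this hypothesis, and whether DNA-PKcs −/− G1 and G2 replicate 1 share a line that G2 replicate 2 does not, could not be checked.

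The CtIP A/A effect on partner deletions over 200 bp differed between DNA-PKcs −/− and DNA-PKcs-present cells by 2.69 points (p = 0.0278, adjusted p = 0.333, exact permutation). Without the G1 libraries of DNA-PKcs-present cells it differed by 1.35 points (p = 0.0556, exact permutation). The null of this planned test was no CtIP effect in either background, so its p does not test the equality of the effects alone.

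Joins onto the bait's own signal side made up 6.17% of substrate junctions in the DNA-PKcs −/− libraries and 2.13% in the others. The stratum-averaged difference was 4.22 points (p = 0.0139, exact permutation), with p = 0.0694 and 0.0972 when wild-type G2 replicate 1 or 2 was left out. The class starts at the heptamer base next to the first coding base, so it includes joins within the signal sequence. Its window also holds the BstBI site at 1904 to 1909.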

How the results depend on the processing

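The trimming at the heptamer borders, the limit to coding-side joins, the removal of telomere repeat and the split by sequencing run were chosen after the results were seen. No measure of the CtIP effect or of the interaction passed the threshold under any alternative that was run. An effect on 1 measure alone could not have passed in any of them. The smallest p of 0.0139 (exact permutation) exceeds 0.05 after adjustment over 12 measures, and some alternatives allow only a larger p. This outcome therefore does not exclude such an effect. Of the 111 planned values of the DNA-PKcs effect other than leaving out a library, 91 stayed on the same side of the threshold with no change of sign in a called value. With G2 libraries only, the DNA-PKcs differences were −43.1 points (substrate), 12.8 bp (median partner deletion), 29.9 and 28.0 points (partner and bait deletions over 20 bp), 18.2 (direct), 18.9 (microhomology) and −37.2 (insertions), with 0 measures past the threshold because 8 libraries allow no p under 0.0556. In run 1 alone they were −50.5, 13, 33.7, 33.8, 17.9, 19.7 and −37.6, and in run 2 alone −30.2, 13.5, 30.04, 31.9, 20.3, 19.3 and −39.6, with 0 past the threshold in either, since the smallest p are 0.5 and 0.125. At 100 bp the DNA-PKcs differences were 1.67 (partner) and 3.62 points (bait) and the phase difference was −2.79, and at 500 bp they were −0.685, 0 and −0.401, because few deletions are that long. With inserted joins left out of the denominator, the direct joins differed by 7.19 and the microhomology joins reversed to −7.19. Without telomere repeat, the substrate difference was −6.28. Microhomology of 4 bp or more differed by −3.12 points with identical junctions counted once, −1.80 after the filter on uncut bases and short alignments and −13.7 without inserted joins, each past the threshold, and reversed to 2.42 with coding-side joins only and trimming at the heptamer borders together (0.883 and −0.0609 with either alone, neither past the threshold). Palindromic insertions passed the threshold on the log odds scale (−1.14), over all substrate junctions (−0.472) and from 2 bp (−3.52). The cause of these shifts was otherwise not tested. The 3 phase measures (median partner deletion, partner deletions over 20 bp, antigen receptor loci) kept their direction but had 0 past the threshold after the filter (−3.63, −11.6 and −5.31), on the log scale (−0.49, −0.75 and −1.09), after thinning (−4.75, −10.3 and −5.03) and in run 2 alone (−3.50, −11.5 and −5.31). Antigen receptor loci without telomere repeat gave −8.17 (adjusted p = 0.0988, exact permutation). Leaving out 1 library gave −4.17 to −2.50 bp, −12.7 to −8.75 points and −6.05 to −4.44 points, with 0 past the threshold each time, as fewer arrangements remain. Phase differences in bait deletions over 20 bp passed the threshold within 200 bp (−10.6), at 10 bp (−10.2) and with coding-side joins and trimming together (−11.8). The DNA-PKcs difference in antigen receptor loci ran from −2.85 to −1.13 points with 1 library left out, past the threshold only without double mutant G2 replicate 2 (−2.85, adjusted p = 0.0208, exact permutation). Counting telomere bait ends once gave a phase difference of 2.83 points (p = 0.0494, exact permutation). In the labels, same-numbered G2 replicates share only a number, and their read names place them in the same sequencing run. They deviated together in some pairs of genotypes and not in others (correlations of −0.0751 to 0.861 over the measures), so they were not taken as pairs. With the replicate block, the DNA-PKcs effect had 8 measures past the threshold (7 without it), the added one being microhomology of 4 bp or more (−1.40, adjusted p = 0.0469, exact permutation), and the CtIP effect and the interaction had 0. No analysis of phase paired by number was possible because the G1 libraries carry none, and run 2 alone pairs each G1 library with the second G2 replicate.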

Other observations

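The tests in this part, other than the planned phase comparison, were chosen after the results were seen.

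The substrate junctions also held joins onto the inverted bait, which the coding-join measures include, and joins onto the signal side of the partner sequence. Joins onto the inverted bait made up 6.78% ± 2.44 (SD, n = 6) of substrate junctions with DNA-PKcs and 4.5% ± 1.28 (SD, n = 6) without it (stratum-averaged difference −2.04 points, p = 0.0278, exact permutation, not adjusted). Joins onto the partner's signal side, the arrangement of a hybrid join, made up 1.14% ± 1.01 with DNA-PKcs and 3.13% ± 3.11 without it (p = 0.0972, exact permutation). The highest share, 8.37% (77 of 920, 95% Wilson interval 6.75 to 10.3), was in the double mutant G2 replicate 2, and DNA-PKcs −/− G2 replicate 2 had 0 of 561 (upper Wilson limit 0.680%).

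In wild-type G1 cells, local clusters of genome joins that overlapped genes took 4.07% of the genome junctions without telomere repeat around Tmem189 on chromosome 2, 2.24% around Mef2d on chromosome 3 and 2.12% around Cyth1 on chromosome 11. Telomere-repeat joins differed by −2.92 points between CtIP genotypes (p = 0.597, exact permutation). Between phases they differed by 7.84 points with every line counted (p = 0.284), by 4.46 points with each event counted once (p = 0.173) and by 2.83 points with each bait end counted once (p = 0.0494, exact permutation, not adjusted).

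Partner deletions were shorter in G2 than in G1 in the 4 genotypes. A difference between the sequencing runs would vanish within 1 run, but within run 2 partner deletions over 20 bp still differed by −11.5 points ± 7.55 (SD, n = 4 genotypes). Different lines behind the G1 and G2 libraries could also give the difference. DNA-PKcs −/− G2 replicate 1, which shares its chromosome 2 cluster with the G1 library, differed from it by −7.01 points, but those libraries were sequenced in different runs, so line and run cannot be told apart there. The time under inhibitor, the drug and the phase itself also stay open as untested, since each differs between the arrests.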
